A study of Mus musculus with 2 samples.

How the data were processed

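The series holds 1 single-cell RNA library and 1 T cell receptor (TCR) library made from the same sorted cells. GD2TIF cells are mouse T cells carrying a Cas9 transgene that received a retrovirus directed against Bcor and Zc3h12a together with 14g2a, a chimeric antigen receptor (CAR) against the ganglioside GD2. Per the labels' protocols, 1000000 of these cells were given to each C57BL/6 mouse with an intact immune system. After 2 months, 1000000 GD2TIF cells were sorted from spleen as CD8+Thy1.1+ cells and loaded on a Singleron microwell chip, where barcoded beads capture the messenger RNA of single cells. How many mice contributed to the sorted cells is not given in the sources used here. There is 1 library of each kind and no other group, so no comparison between treated and untreated cells is possible. Cells were not treated as replicates, and no test between groups of cells was run.

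The deposited RNA matrix holds raw UMI counts per gene and cell barcode, not normalized, and every value in it was a whole number. The submitters' processing notes name cutadapt 1.17, STAR 2.6.1a, featureCounts 2.0.1 and the genome build GRCm38, with no role or order. The deposited contig table gives a count of UMIs and of reads for each assembled TCR contig, and its length in bases, which was not used here. The deposited clonotype table gives the count of barcodes per clonotype and that count as a percent of all barcodes with a clonotype, rounded by the authors to 1 decimal. Shares were recomputed from the counts. The V(D)J assembler is not given in the sources used here. The shallowest barcode of the RNA matrix had 500 UMIs, and cells below this depth are not analysed here.

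Cells were kept with at least 200 genes and under 20% mitochondrial UMIs. Of 10387 barcodes, 4 had under 200 genes and 47 had 20% or more mitochondrial UMIs, so 49 failed the filter. The doublet caller scrublet marked 1 further barcode, 0.00967% of those tested, which is too few for a caller that worked on this number of cells. Doublets were therefore treated as present, and barcodes with 2 productive TRB sequences were left out in an alternative. That alternative also leaves out families whose cells carry 2 TRB, as given below. The filter left 10337 cells, in which 20773 of the 20794 genes of the matrix had a UMI. Cd244a, a gene of the fixed lists, stands under its older symbol in the matrix and was matched by its gene identifier.

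Counts of a gene were summed over cells and divided by the sum of all UMIs to give counts per 1000000 UMIs (CPM). Sums have exact Poisson 95% intervals, ratios of sums have exact conditional intervals, and shares of cells have exact Clopper-Pearson intervals. A count of 0 was set against a floor of 3 counts over the group. All these intervals cover counting error only, not the spread between mice or libraries. Gene lists were set apart from other genes only by the percentile of their median fold among 10000 random lists of the same size matched on expression, as a description of these libraries.

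Clusters were made with scanpy 1.11.5 and igraph 0.11.9 under python 3.11.15, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19. The 2000 most variable genes entered, leaving out TCR segment, immunoglobulin, mitochondrial and ribosomal genes. There were 30 principal components, 15 neighbours and a Leiden resolution of 0.8. A cluster was named after a cell type only where at least 3 fixed markers were raised. Raised means at least 2-fold over other cells and present in at least 10% of the cluster's cells. A marker of that type also had to be among its 10 leading genes by fold. For this rule the antigen presentation genes Cd74, H2-Aa and H2-Ab1, which B cells share with dendritic cells, were set aside, a choice made after the clusters had been seen. Cells of other types were counted as cells with at least 2 different markers of a type. Cycling cells were counted the same way after each cell had been thinned to 1000 UMIs.

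Clonotypes are those of the deposited table. A TRB lineage here means the cells kept in the RNA library with exactly 1 productive TRB contig, grouped by its CDR3 nucleotide sequence, a grouping added after the data had been seen. The lineages leave out cells with 2 TRB, also where a family carries both. The RNA and TCR libraries were joined on the barcode. Each of the 3 largest clonotypes was set against all other cells with a clonotype, and cells of clonotypes of at least 10 cells were set against cells of clonotypes of 1 or 2 cells. The planned comparison of cycling-like cells with other cells was not run, because no cluster met the markers of cycling cells.

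Genes are named by a rule fixed before the data were examined. Every gene of the fixed lists may be named. In each comparison of cells, the rule takes the 15 genes with the largest fold higher and the 10 with the largest fold lower. These must have at least 200 UMIs over both sides, a fold of at least 1.5 and intervals that do not overlap, and TCR, immunoglobulin, mitochondrial and ribosomal genes and unnamed gene models are left out. Some genes that the rule takes are not reported here. The 5 most used V genes of each chain and the 5 largest clonotypes are also named. The lists cover T cell identity, cytotoxic molecules, cytokines and chemokines, inhibitory, costimulatory and cytokine receptors, memory and stemness, effector and exhaustion transcription factors and NK receptors. They further cover homing and adhesion, proliferation, survival and death, transcripts bound by Regnase-1, glycolysis, oxidative phosphorylation, interferon response, immediate early and heat shock genes, the Polycomb group with Bcor, and sex-linked genes.

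The ratio intervals were tested on simulated counts with known folds, drawn for the comparison of the largest clonotype over 6271 genes. The intervals of the groups did not overlap for 71.6% of genes changed 1.5-fold, 95% of those changed 2-fold, 100% of those changed 4-fold and 1.22% of unchanged genes. Alternatives varied the cell filter, the weight of cells, the clustering, the number of markers, the depth, the clonotype definition and the size limits. Gene positions come from the RefSeq gene table of assembly GRCm38.p6.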

Results

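The RNA library gave 10337 cells after filtering, with a median of 1922 UMIs and 977 genes per cell. The 5th and 95th percentiles were 815 and 4244 UMIs, and the median mitochondrial share was 3.53%. Ribosomal protein genes took 19.0% of all UMIs, Gm42418, a model over ribosomal RNA, 3.25% and the nuclear transcript Malat1 1.24%. At this depth 3 UMIs over all cells correspond to 0.135 CPM. The TCR library gave 5479 barcodes with a clonotype. Each library stands alone, so no value below has a replicate, and all intervals are 95% and cover counting error only.

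The transcripts of both edited genes were present. Bcor, a corepressor of the noncanonical Polycomb complex, stood at 171 CPM (166 to 177), and Zc3h12a, which encodes the RNA-degrading enzyme Regnase-1, at 47.5 CPM (44.6 to 50.4). An edit in the coding sequence need not remove a transcript, so these levels do not check the edit.

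The sorted cells carried the transcripts of CD8 T cells, and 14 of the 15 T cell identity genes were at 100 CPM or more. Trbc2 was at 3576 CPM, Trbc1 at 2682, Cd3e at 1471, Cd8b1 at 407 and Cd8a at 208, while the costimulatory receptor gene Cd28 was the lowest at 86.9. Genes of memory and stemness were all detected, 10 of 15 at 100 CPM or more. They were led by Klf2 at 2611 CPM, a transcription factor that keeps T cells in circulation, and by Tcf7 at 626, the transcription factor of stem-like T cells. Slamf6 was at 440.2 CPM, Lef1 at 375 and Id3 at 254, and Myb was lowest at 16.9.

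Transcription factors of effector and exhausted T cells were present beside these memory genes. Of 18 genes, 7 were at 100 CPM or more, led by Tox at 649 CPM, a factor of chronically stimulated T cells, Batf at 588, Nfatc1 at 421 and Runx3 at 277. Tbx21, which encodes the effector factor T-bet, was at 96.2 CPM and Zfp683 at 0.359. Of the 12 inhibitory receptors, Pdcd1, which encodes PD-1, was at 337 CPM, Lag3 at 227, Vsir at 200.1 and Ctla4 at 108, and Tigit followed at 81.4. Havcr2, which encodes the late exhaustion receptor TIM-3, was at 6.82 CPM, Entpd1 at 4.13 and Klrg1, a receptor of terminal effector cells, at 2.11.

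Cytotoxic genes were split by level. The granule gene Nkg7 was at 2456 CPM, Srgn at 529, Ctsw at 385, the granzyme gene Gzmk at 333 and perforin (Prf1) at 219.5, while Gzmb was at 14.2 and Gzma at 13.5. Gzmc had 1 UMI. Among 13 measured cytokines and chemokines, Ccl5 was at 1058 CPM, Ltb at 512, Xcl1 at 198 and Ifng at 104. Il2 was at 19.3 CPM, Tnf at 7.18, Il4 had 3 UMIs and Il13 had 2.

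Receptor genes also ranged widely. The costimulatory receptors Cd27 and Icos were at 564 and 429 CPM, and Cd2 at 163, while Tnfrsf4, which encodes OX40, was at 1.57. The shared cytokine receptor chains Il2rb and Il2rg were at 614 and 576 CPM and Il7r at 82.3, whereas the high-affinity interleukin 2 receptor chain Il2ra was at 0.180 and Il1rl1 had 1 UMI. Of 19 homing and adhesion genes, 10 were at 100 CPM or more, among them Itga4 at 462, Selplg at 387.5 and Itgal at 250.4. The gut homing receptor Ccr9 and the egress receptor S1pr5 had 2 UMIs each. All 15 measured NK receptor genes were under 10 CPM, with Klrd1 highest at 9.83 and Klrb1f next at 5.25.

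Among transcripts that Regnase-1 is known to bind, Icos was at 429 CPM, Nfkbiz at 337, Ctla4 at 108, Rel at 73.2 and Il2 at 19.3. Of the 9 Polycomb genes listed with Bcor, Skp1a was at 321 CPM, Rnf2 at 127 and the paralog Bcorl1 at 9.61. Glycolytic genes were led by Gapdh at 878 CPM, Aldoa at 482 and Pkm at 394, and 7 of 15 were at 100 CPM or more. For oxidative phosphorylation this was 13 of 16, with Ndufa4 at 771 CPM and Atp5e at 723. Survival genes included the antiapoptotic Bcl2 at 329 CPM and Mcl1 at 239, the proapoptotic Bax at 249.7, and the death receptor Fas at 3.82. Immediate early and heat shock genes were high, with Junb at 1242 CPM, Jund at 1138 and Hspa1a at 1029. Interferon response genes were mostly low apart from Ifi27l2a at 247 CPM. Over all lists, 106 genes were at 100 CPM or more.

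Few cells carried cycle transcripts. After thinning to 1000 UMIs, 22 of 9455 cells (0.233%, 0.146 to 0.352) had at least 2 markers of cycling, and 882 shallower cells were left out. Without thinning, 75 of 10337 cells (0.726%) did. The proliferation genes Top2a and Mki67 were at 10.7 and 6.51 CPM and Cenpf at 0.314, whereas Hmgb2 and Pcna, which resting cells also transcribe, were at 412 and 123.

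Xist, the transcript of the inactive X chromosome in female cells, was at 288.5 CPM, with a UMI in 37.4% of cells (36.5 to 38.3), and in 22.4% after thinning. Y-linked genes were near the floor. Ddx3y was at 0.359 CPM and Eif2s3y at 0.314, Kdm5d and Uty had 1 UMI each, and 12 cells (0.116%) had a Y-linked UMI.

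Clustering asked whether the sorted cells were of 1 kind, and gave 11 clusters. The largest 4 held 2559, 2344, 2070 and 1966 cells and were not named after a type, because none of the fixed marker sets was raised in them. Cluster 1 was led by Prg4, Izumo1r and Sostdc1, and cluster 2, with a median of 1382.5 UMIs, by Gpr183, a receptor that guides cells within the spleen. Cluster 3 was led by Ly6a, Serpina3g, Ly6c2 and the interferon-inducible GTPases Iigp1 and Tgtp2. Cluster 4 was led by Mvd, an enzyme of the mevalonate pathway, Osr2, Coch, Serpine2, Maf, Esm1 and Gzmb. In cluster 4 Pdcd1 was at 624 CPM, Gzmk at 851 and Ctla4 at 240, and Tcf7 was at 272, against 725 to 770 in clusters 1 to 3. Tox was between 585 and 813 CPM in clusters 1 to 10.

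Smaller clusters were more distinct. Cluster 5 (5.24%) was led by Bbs9, Egr3 and Srm, with Xcl1 at 590 CPM, and cluster 8 (1.15%) by the metallothioneins Mt1 and Mt2. Cluster 6 (4.24%) had a median of 953.5 UMIs, 9.36% mitochondrial UMIs and nuclear transcripts such as Xist and Kcnq1ot1 among its leading genes. Cluster 7 held 177 cells (1.71%, 1.47 to 1.98) and met the markers of effector CD8 T cells, with Gzma, Gzmb, Prf1, Fasl and Nkg7 raised. Of the markers of exhausted CD8 T cells, Pdcd1, Havcr2, Lag3, Tigit, Cd244a and Nr4a2 were raised there too. Ccl5 there was at 14163 CPM against 798 elsewhere, Gzma at 503 against 3.75, Ccl4 at 1074 against 7.97 and Cxcr6, a chemokine receptor of tissue-dwelling T cells, at 1049 against 28.6. The exhaustion receptors Pdcd1 and Havcr2 were at 1395 and 92.2 CPM in this cluster, and Tcf7 at 83.0. Cluster 10 (38 cells, 0.368%) was interferon responding-like, with all 10 markers detected and Ifit3 at 1476 CPM against 8.38. The effector-like class is not stable, since it took 918 to 2071 cells in the 5 alternative clusterings, and the interferon responding-like class took 32 to 162. The adjusted Rand index of these clusterings with the 11 clusters was 0.364 to 0.560.

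Markers of cells outside the gate were also counted. The 29 cells of cluster 11 (0.281%) were B cell-like, with Cd79a at 1088 CPM against 0.540 in other cells and Ms4a1 at 851 against 0.495. At least 2 B cell markers were found in 1255 cells (12.1%, 11.5 to 12.8), but in 116 with at least 3 markers. This was carried by the immunoglobulin gene Ighm at 560.5 CPM, which lay between 221 and 1089 CPM in the 10 other clusters and at 28036 in cluster 11, while Cd79a was at 4.04 over all cells. NK markers were found in 587 cells (5.68%), for which 1 marker is Eomes, a factor of memory CD8 T cells as well, and in 5 cells with at least 3 markers. Markers of CD4 or regulatory T cells were found in 901 cells (8.72%), although Cd4 was at 0.629 CPM and Foxp3 at 0.180, and that set holds Ctla4 and Ikzf2, the latter at 230.3 CPM. Monocyte markers were found in 43 cells (0.416%), erythroid in 17 and stromal in 5. Of 8 neutrophil markers only Ly6g, Cxcr2 and Ngp were in the matrix, with 1 UMI each, and 0 of 10337 cells had 2 of them, which sets no limit on neutrophils, since the other 5 could not be counted. Of the gamma delta T cell markers and the platelet markers only 1 each was in the matrix (Trdc and Itga2b), and of the mast cell markers none, so these could not be counted. Every gene in the matrix had a UMI in at least 1 barcode. Absent markers may therefore have had none, but why they are absent is not given. Of 3446 haemoglobin UMIs, 3138 (91.1%) came from 1 barcode with 3738 UMIs in all.

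The TCR library shows which receptor chains the transferred population carried after 2 months. The 5479 barcodes fell into 1250 clonotypes, of which 864 (69.1%) were seen in 1 cell. These are not 1250 families, since there were 484 distinct TRB and 551 distinct TRA sequences. Of the clonotypes 113 had no TRA and 253 no TRB, and a missing or additional chain puts cells of 1 family into several clonotypes. This raises the number of clonotypes, the number seen in 1 cell and the inverse Simpson number. The largest held 524 cells (9.56%, 8.80 to 10.4) and the 10 largest 1710 cells (31.2%). The 84 clonotypes of at least 10 cells held 62.2% of cells, and the inverse Simpson number was 56.6. Clonotype 1 paired the TRA CDR3 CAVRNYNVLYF with the TRB CDR3 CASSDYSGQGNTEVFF. Clonotype 2 (300 cells, 5.48%) paired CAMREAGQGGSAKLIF with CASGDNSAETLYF, and clonotype 3 (164 cells, 2.99%) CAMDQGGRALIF with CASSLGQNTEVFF. Clonotype 4 (150 cells, 2.74%) was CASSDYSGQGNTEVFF without a TRA, and clonotype 5 (146 cells) paired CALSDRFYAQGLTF with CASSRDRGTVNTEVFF.

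Counting TRB sequences alone gave larger families. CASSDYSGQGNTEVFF was carried by 1051 of 4559 barcodes with a TRB (23.1%, 21.8 to 24.3) and was spread over 38 deposited clonotypes, and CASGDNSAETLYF by 693 (15.2%) over 29. With TRB nucleotide sequence alone, and each barcode given its TRB of most UMIs, 473 of the 484 TRB sequences made a clonotype, the largest held 22.4% of cells, and the inverse Simpson number was 11.9. Exactly 1 TRA and 1 TRB were found in 3110 barcodes (56.8%, 55.4 to 58.1), TRA alone in 851 (15.5%) and TRB alone in 606 (11.1%). A barcode held 2 TRB in 247 cases (4.51%, 3.97 to 5.09). The same 2 TRB recurred with 1 TRA in clonotype 12 (56 cells, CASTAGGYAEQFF and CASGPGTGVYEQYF). They did so too in clonotype 16 (47 RNA cells, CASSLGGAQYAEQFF and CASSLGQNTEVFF). Thus 2 TRB do not by themselves mark a doublet. As TRB lineages, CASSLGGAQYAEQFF and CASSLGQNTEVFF count apart.

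**Figure D1:**
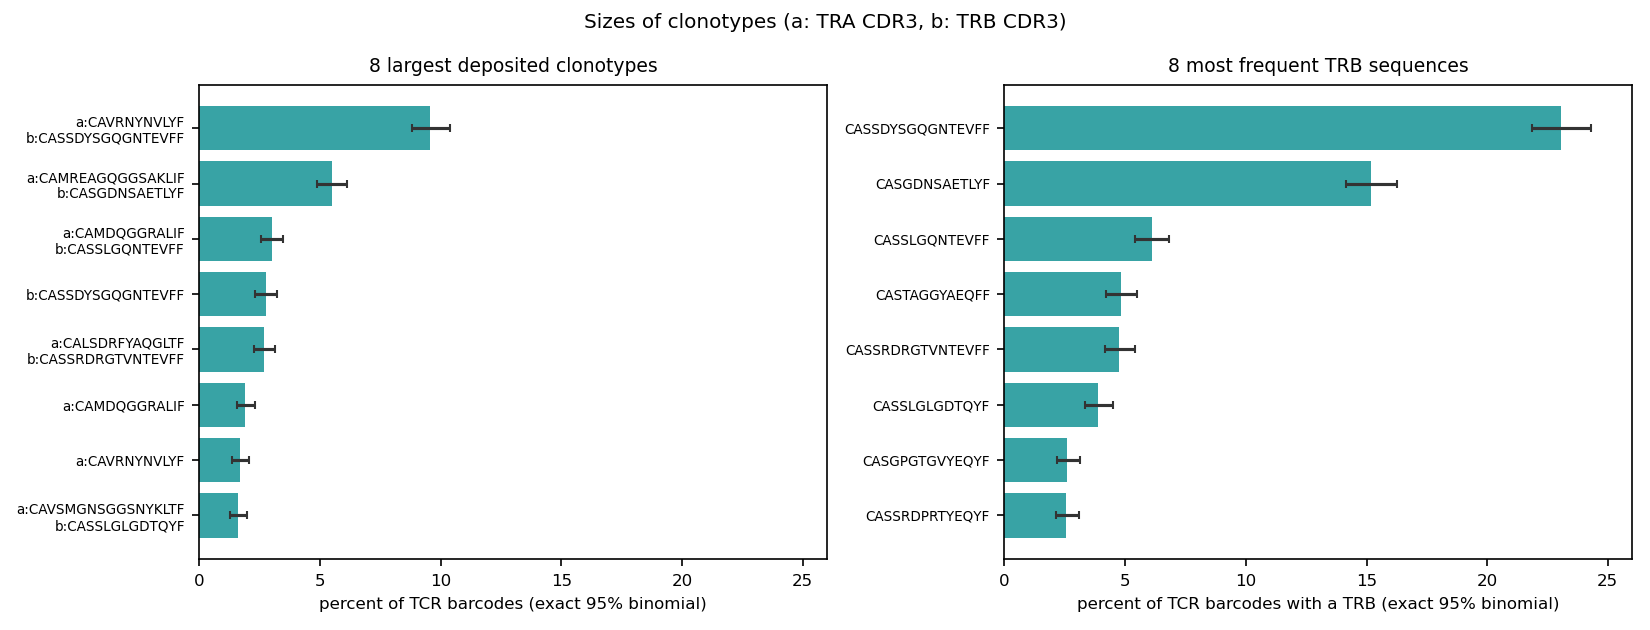
Share of barcodes held by the 8 largest deposited clonotypes and by the 8 most frequent TRB sequences, in percent with exact binomial 95% intervals. The largest clonotype holds 9.56% of 5479 barcodes and the most frequent TRB 23.1% of 4559.

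The V genes followed the largest families. TRBV15 took 27.3% of cells with a TRB but 8.43% with each clonotype counted once, and 17.8% without the largest clonotype. TRBV12-2+TRBV13-2 took 20.1%, TRBV29 8.42%, TRBV17 7.90% and TRBV13-3 7.76%. Among TRA, TRAV3D-3 took 18.5% of cells and 6.07% with each clonotype counted once, or 8.64% without the largest clonotype. TRAV13N-1 took 12.4%, TRAV16D-DV11 11.3%, TRAV6-7-DV9 7.32% and TRAV5-4 4.36%. By cells TRBJ1-1 was the most used J gene of the TRB chain at 39.5% and TRBJ2-3 was next at 17.2%. With each of the 473 TRB sequences counted once TRBJ2-7 led at 18.2%, with TRBJ1-1 at 14.4% and TRBJ2-3 at 9.73%. The TRB CDR3 had a mean length of 14.2 amino acids (SD 1.47 over 4559 cells) and the TRA CDR3 of 13.3 (SD 1.87 over 4864 cells).

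Joining the libraries placed a clonotype on 4585 of 10337 RNA cells (44.4%, 43.4 to 45.3). Cells with a clonotype had a median of 2032 UMIs and cells without of 1827. The TRB V gene seen in the RNA equalled that of the contig in 511 of 832 cells (61.4%, 58.0 to 64.7), against 18.8% with barcodes shuffled. For TRA it did in 364 of 739 (49.3%, 45.6 to 52.9), against 3.38%. The Trbc1 share of TRBC UMIs was 77.3% in cells with a TRBC1 contig and 10.5% in cells with a TRBC2 contig.

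Clonotypes did not spread evenly over the clusters. Of 20 clonotypes with at least 30 cells, 15 had the majority of their cells in 1 cluster, and the share in the main cluster ranged from 37.2% to 86.0%. Clonotype 1 lay in cluster 4 with 83.9% of its cells (80.5 to 87.0), where 23.0% of all cells with a clonotype lay. Clonotype 2 lay in cluster 3 with 85.3% (80.8 to 89.1), against 21.3%. Counted as TRB lineages, 12 of 19 had their majority in 1 cluster. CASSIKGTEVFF, with 34 cells, had 67.6% (49.5 to 82.6) in cluster 5, against 4.66% of all lineage cells. These clusters were led by genes that also mark the families, Mvd in cluster 4, Ly6a in cluster 3 and Bbs9 in cluster 5, so these shares and the genes named below are not separate evidence. At resolution 1.2 the clonotypes with a majority in 1 cluster came to 25% in place of 75%.

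**Figure D2:**
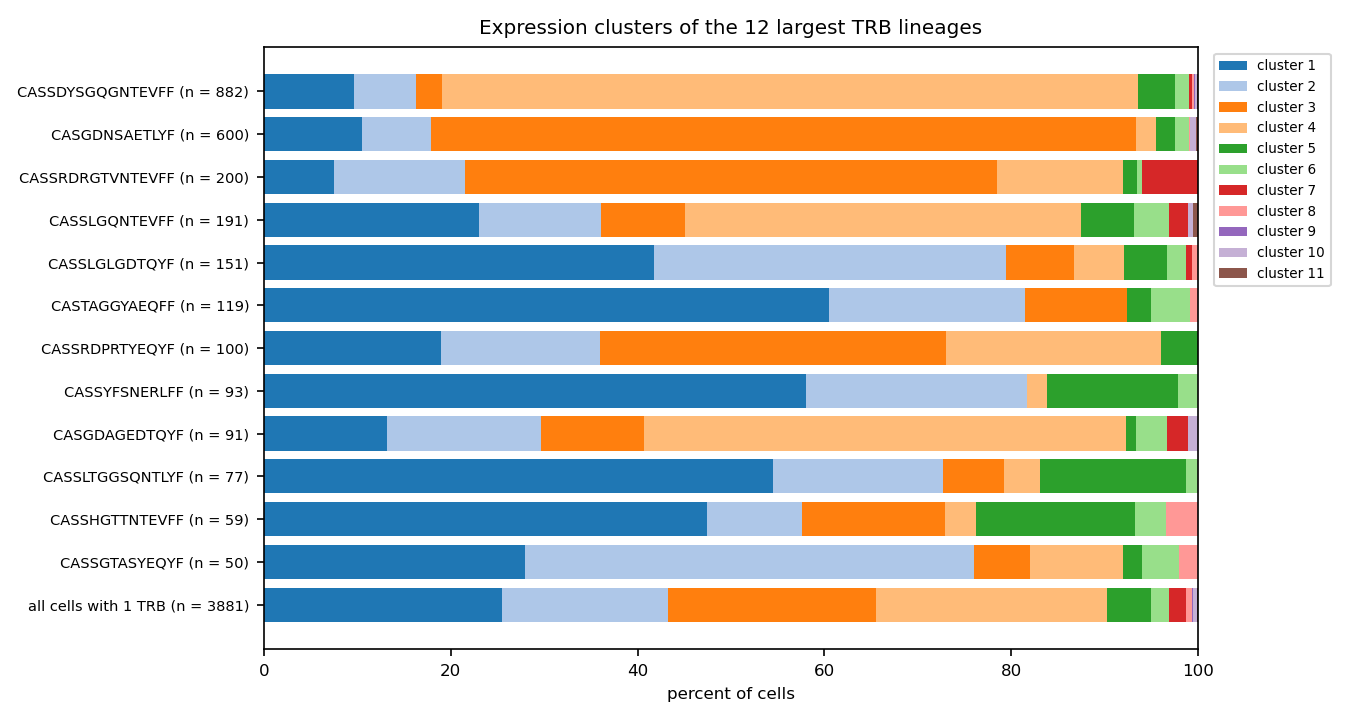
Share of cells in each cluster, in percent, for the 12 largest TRB lineages and for all 3881 cells with 1 TRB, as stacked bars. The lineage with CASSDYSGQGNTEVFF has 74.5% of its cells in cluster 4 and the lineage with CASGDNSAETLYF 75.5% in cluster 3.

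Clonotype 1 differed from the others by single genes and by receptor and memory programmes. Mvd, an enzyme of the mevalonate pathway, was 12.6-fold higher (10.8 to 14.7), at 393 CPM in 517 cells against 31.1 CPM in 4068 cells. Esm1 was 9.72-fold higher (8.03 to 11.8), the transcription factors Osr2 and Twist1 8.22-fold and 6.18-fold, and Maf, which drives interleukin 10 and interleukin 21 in T cells, 4.65-fold (3.94 to 5.49). Gzmk was 3.71-fold higher (3.47 to 3.97), at 1105 against 298 CPM. Tcf7 was at 0.480 of the level in the others, at 312 against 649.6 CPM.

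The named genes of clonotype 1 also held Nudt10 at 4.47-fold, Ctla2a at 532 against 127 CPM, Mest at 4.17-fold, Dkk3 at 3.97-fold, Pms1 at 3.78-fold, Cybb at 3.77-fold and Coch at 3.59-fold. Lower, after the haemoglobin genes that came from 1 barcode of clonotype 2, were Wls at 0.0525, Serpina3g at 0.0688, the chemokine receptor Xcr1 at 0.0812, Ly6c2 at 0.0841, Dpp4 at 0.0887 and H2-Ob at 0.0926. Inhibitory receptors had a median fold of 1.44 (percentile 100), with Ctla4 at 3.08-fold (2.71 to 3.50), Entpd1 at 3.68-fold, Lag3 at 1.75-fold and Pdcd1 at 1.66-fold (1.52 to 1.81). Effector and exhaustion transcription factors had a median of 1.42 (percentile 100), with Irf4 at 5.06-fold, Prdm1 at 2.90-fold and Tox at 778 against 649 CPM. Transcripts bound by Regnase-1 had a median of 1.36 (percentile 99.8), with Icos at 2.05-fold, and of 1.18 (percentile 96.7) counted as the TRB lineage. Il21, a cytokine of helper T cells, was at 32.6 against 3.84 CPM. Memory and stemness genes had a median of 0.816 and cytokine receptors of 0.758 (percentile 0.04 each), with Il7r at 0.300. Bcor was at 0.618 (0.510 to 0.743).

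Clonotype 1 carries a TRBC1 receptor, and Trbc1 was 3.82-fold higher with Trbc2 at 0.258. Counted as the TRB lineage, 882 cells against 2999, Mvd was 27.2-fold, Osr2 12.4-fold and Pms1 5.82-fold higher, and Serpina3g, Xcr1, Ly6c2, Dpp4 and H2-Ob lay between 0.162 and 0.265. With the other large clonotypes weighted equally Mvd was 6.21-fold, Osr2 4.77-fold, Esm1 3.95-fold, Twist1 3.25-fold, Ctla2a 2.57-fold and Dkk3 2.09-fold higher. How many mice gave the cells is not known, so differences between clonotypes here and below are not separated from differences between mice.

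Clonotype 2 carried more transcripts of Ly6a and of several interferon-inducible genes. Ly6a, which encodes the surface protein Sca-1, was 4.76-fold higher (4.22 to 5.35), at 484 CPM in 299 cells against 102 in 4286. The interferon-inducible GTPases Tgtp1, Tgtp2 and Iigp1 were 4.02-fold, 2.92-fold and 2.72-fold higher, Ifi213 3.32-fold and Rtp4 2.65-fold. Ccl5 was at 0.149 of the level in the others (0.125 to 0.175), at 173 against 1166 CPM, and Lag3 at 0.301, at 74.1 against 246 CPM.

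Further genes of clonotype 2 were Gpm6b at 3.58-fold, Ifit1bl1 at 3.32-fold, Serpina3g at 2.81-fold, Xcr1 at 2.73-fold and Cxcr3, a chemokine receptor for interferon-induced ligands, at 2.67-fold. Lower were the protease inhibitor Serpine2 at 0.0256, Osr2 at 0.0477, Coch at 0.0530, Mt1 at 0.0839, Spp1 at 0.0887, Cxcr6 at 0.0971 and Capg at 0.104. Effector and exhaustion transcription factors had a median fold of 0.618 (percentile 0), with Maf at 0.146 and Ikzf2 at 0.422. Inhibitory receptors had a median of 0.717 (percentile 0.19), with Pdcd1 at 0.514. Immediate early and heat shock genes had a median of 1.51 (percentile 100), with Hspa1a at 2317 against 891 CPM, and homing genes of 1.33 (percentile 100), with Itgb7 at 2.10-fold. Interferon response genes had a median of 1.27 (percentile 99.6), and transcripts bound by Regnase-1 of 0.868 (percentile 10.2). Counted as the TRB lineage, 600 cells against 3281, Gpm6b was 5.98-fold higher, and Serpine2 was at 0.0571, Osr2 at 0.120, Spp1 at 0.146, Capg at 0.214 and Mt1 at 0.718. With the other large clonotypes weighted equally Gpm6b was 2.23-fold higher and Mt1 at 0.299. Hbb-bt, Hba-a2, Hba-a1 and Hbb-bs led the list by fold, with Hbb-bt at 916-fold, and came from the 1 barcode named above.

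Clonotype 3 carried more transcripts of Cxcr6, of Ccl5 and of the cycle genes Pclaf, Mki67 and Stmn1. Cxcr6 was 3.94-fold higher (2.96 to 5.16), at 162 CPM in 160 cells against 41.2 in 4425, and Ccl5 2.16-fold, at 2248 against 1041 CPM. Pclaf, a partner of the replication clamp, was at 63.8 against 4.45 CPM, Mki67 at 34.5 against 6.07, and Pdcd1 at 598 against 343.5. Gzmk was at 0.301, and Tcf7 was at 0.656.

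Also higher in clonotype 3 were Coch at 3.85-fold, Enpp2 at 3.76-fold, Serpine2 at 3.66-fold, Bcl9l at 3.38-fold, Twsg1 at 2.93-fold, Gsn at 2.84-fold, Stmn1 at 2.66-fold, Tox2 at 2.64-fold and the death ligand gene Tnfsf10 at 2.59-fold. Dapl1, Tgtp1 and Mest had 0 UMIs in clonotype 3, which puts their ratios at 0.293, 0.377 and 0.390 at most with 3 counts as the floor. Zfp217 was at 0.0858 and Mt1 at 0.0974. Proliferation genes had a median of 1.45 (percentile 99.85), cytokines and chemokines of 0.900 (percentile 19.5) and memory genes of 0.736 (percentile 0). Of 11 measured proliferation genes, 4 were higher with intervals that did not overlap and 7 had overlapping intervals. Pclaf and Mki67 rest on 24 and 13 UMIs in clonotype 3, which few cells could give. Immediate early genes had a median of 0.769 (percentile 0), with Jun at 0.511, and transcripts bound by Regnase-1 of 1.05 (percentile 72.1). Counted as the TRB lineage Mt1 was at 0.285 and Mest at 0.105, and with the other large clonotypes weighted equally Mt1 was at 0.333.

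The spread between families was set beside random portions of 15 cells from the same family, over 1642 genes. A portion of a TRB lineage correlated best with the other portion of the same lineage in 12 of 19 lineages, where chance gives 1. For deposited clonotypes this was so in 7 of 20. Each lineage was also marked by the gene with the largest fold over the other lineages, a choice made after the data were seen. Jaml, an adhesion molecule of T cells, was at 615 CPM in the 37 cells with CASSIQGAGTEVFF against 0.459 in other lineages. Mylpf, a light chain of fast muscle myosin, was at 2053 CPM in the 35 cells with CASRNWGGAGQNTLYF against 13.6, a 151-fold difference (117 to 194). Bbs9 was at 383 against 7.60 CPM in the lineage with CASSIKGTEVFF, and Pigx at 991 against 63.0 in that with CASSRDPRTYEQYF. In GRCm38, Jaml lies on chromosome 9 from 45079153 to 45108531 and Mylpf on chromosome 7 from 127208848 to 127214288.

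**Figure D3:**
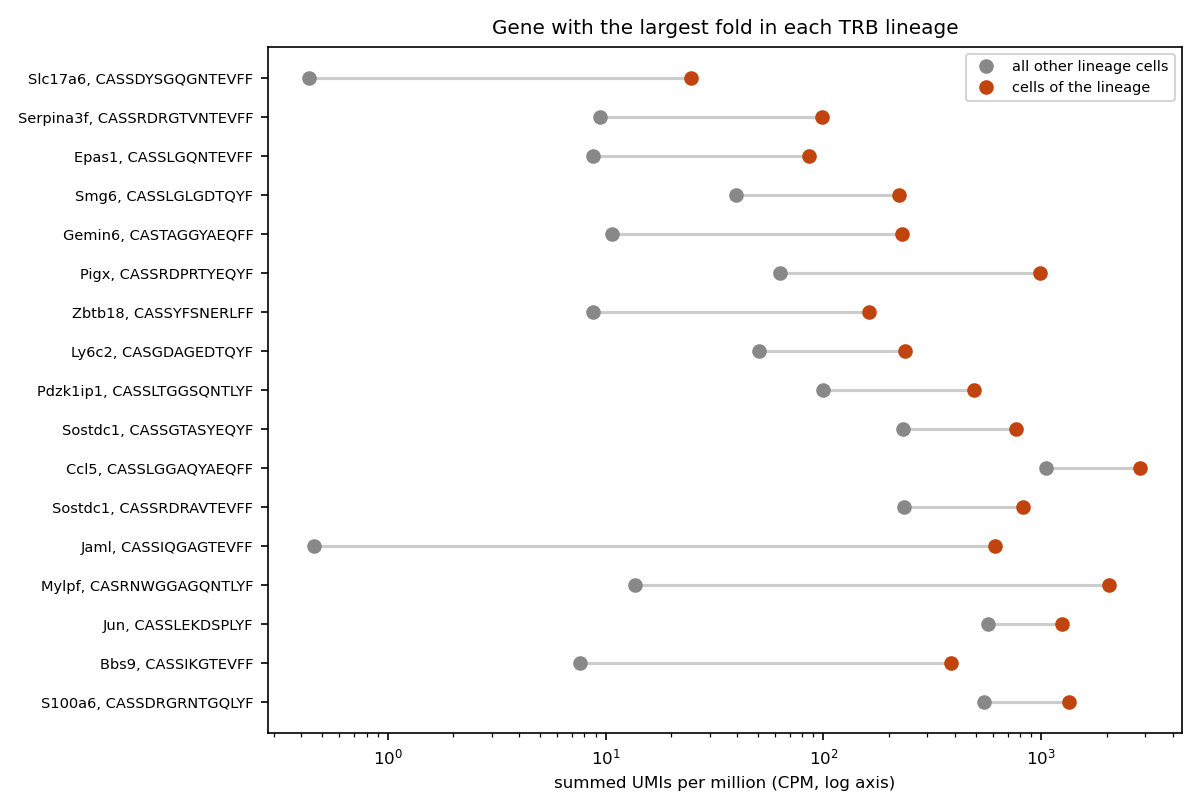
The gene with the largest fold in each of 17 TRB lineages, in CPM on a log axis, in the lineage and in all other lineage cells, with 2 lineages left out whose gene came mostly from 1 cell. Jaml stands at 615 against 0.459 CPM and Mylpf at 2053 against 13.6.

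Expanded and small clonotypes were compared to see whether clonotype size went with a state. Small deposited clonotypes can include cells of large families with a missing or additional chain. Counted as TRB lineages, 3227 cells stood in expanded families and 399 in small ones. Mvd was 8.10-fold higher (5.35 to 12.9) in the 2803 cells of expanded clonotypes than in the 910 cells of small ones, at 98.9 against 12.2 CPM, and Esm1 was 6.84-fold and Dkk3 6.66-fold higher. Gzmk was at 465.5 against 223 CPM and Ctla4 was 1.67-fold higher. Small clonotypes had more of Dapl1, a gene of resting memory T cells, at 62.2 against 16.6 CPM (ratio 0.267, 0.204 to 0.351). They also had more of the chemokine receptor gene Cxcr6 at 103 against 29.5 CPM, of Il7r at 123 against 53.9, and of Ccl5 at 1687 against 942.

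Among further genes higher in expanded clonotypes, Osr2 was at 5.29-fold, Cybb at 4.92-fold, Tprg at 4.22-fold, Ctla2a at 4.02-fold, Twist1 at 3.02-fold and Nudt10 at 2.98-fold. Lower were Gpr183 at 0.439, Pip4k2b at 22.1 against 44.1 CPM, Slfn5 at 0.506, Rbpj at 0.558, Fmnl3 at 0.576 and Klhl6 at 0.582. Cytokines and chemokines had a median of 0.742 (percentile 0), with Ccl4 at 0.218 and Ccl3 at 0.268, and the granzyme gene Gzma was at 5.75 against 36.1 CPM. Memory genes had a median of 0.945 (percentile 3.01), and costimulatory receptors of 1.13 (percentile 98.5), with Icos at 1.40-fold. Transcripts bound by Regnase-1 had a median of 1.06 (percentile 79.3). Hbb-bt was 71.6-fold higher from the 1 barcode with most haemoglobin. With families counted as TRB lineages it had 0 UMIs in small ones and was at least 8.82-fold higher against a floor of 3 counts. Cd74, an antigen presentation gene abundant in B cells, was 3.63-fold higher, at 67.4 against 18.6 CPM, but 2.31-fold with barcodes of 2 TRB left out and at 0.406 (0.251 to 0.682) with families counted as TRB lineages. With families counted as TRB lineages Esm1 was 15.1-fold, Osr2 14.1-fold and Mvd 6.71-fold higher, and Ccl5 was at 0.380. Without the largest clonotype Mvd was 2.95-fold, Esm1 3.26-fold, Osr2 2.55-fold and Nudt10 1.97-fold higher. Twist1 was then at 1.64 (0.975 to 2.90), whose interval includes 1. Other clonotypes with the TRB of the largest stayed in. In cells outside that TRB lineage Mvd was at 11.8, Esm1 at 13.7 and Osr2 at 21.9 CPM. In small clonotypes they were at 12.2, 9.03 and 17.5 CPM, so the folds of these genes rest largely on that 1 family.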

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

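No test was run in this part, and its values describe TCR barcodes without RNA and contigs that were left out above.

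TCR contigs were found for 889 barcodes that have no column in the RNA matrix, 16.2% of all barcodes with a clonotype. They had a median of 5 contig UMIs against 61 for TCR barcodes kept in the RNA library. Exactly 1 TRA and 1 TRB were found in 6.75% of them, against 66.5% of the kept barcodes. They count toward the clonotype numbers, sizes and V gene shares above, and their own RNA enters no comparison. Through the sizes they also help to set which RNA cells belong to expanded or small clonotypes, 2803 and 910 cells above, against 2716 and 943 with sizes over barcodes kept in the RNA library.

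The contig table holds 28030 non-productive contigs, 73.0% of all 38397, which no comparison above used. Their median was 5 UMIs against 10 for the 10367 productive contigs. A CDR3 was given for 10743 of them, and in 8244 it equalled the CDR3 of a productive contig of the same chain. The table also holds 63 contigs that join segments of different chains.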

How the results depend on the processing

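The alternatives by TRB lineage, by TRB sequence among RNA-kept barcodes, by clonotype size in RNA-kept barcodes and without the haemoglobin-rich barcode, alone or with B cell-like cells, were chosen after seeing the data. Of the values that answer a comparison, 60 stayed within their counting interval or within 1.5 times their count, and 36 moved. Of single values among many, 386 stayed, 57 moved and 6 reversed. For TRB lineages Cd74, whose level rests on few B cell-like barcodes, turned from higher in expanded families to 0.406. Without the haemoglobin-rich barcode Hba-a2, Hba-a1 and Hbb-bs turned to 1.34, 1.15 and 1.22 in clonotype 1, and Hbb-bs to 0.679 in clonotype 2 and 0.465 in expanded clonotypes. List genes at 100 CPM or more were 103 to 106 in the alternatives. The cause of the moves was not tested beyond what each alternative changes by construction.

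At resolution 1.2 there were 18 clusters, and 25% of large clonotypes had their majority in 1. With at least 3 markers, B cell markers were found in 116 cells, NK in 5, erythroid in 7 and monocyte in 1, and the cycling share was 0.0423%. It was 0.726% without thinning and 0.0967% after thinning to 500 UMIs. Thinning put Xist at 22.4% of cells. The number of clonotypes, the share of the largest, the share of the 10 largest and the inverse Simpson number were 473, 22.4%, 63.9% and 11.9 by TRB sequence alone. They were 616, 16.8%, 47.0% and 21.5 for cells with 1 TRA and 1 TRB, 446, 21.8%, 63.6% and 12.1 by TRB among RNA-kept barcodes, and 432, 22.7%, 64.5% and 11.5 for TRB lineages. The largest deposited clonotype held 11.3% of RNA-kept barcodes. With each clonotype once, TRBV15 took 8.43% and TRAV3D-3 6.07%, and without the largest clonotype 17.8% and 8.64%. For TRB lineages Mvd was 27.2-fold higher in the largest, Ly6a 6.15-fold in the next, and Hbb-bt at least 8.82-fold in expanded families, with 0 UMIs in small ones. Mvd was 6.21-fold higher with other clonotypes weighted equally, and 2.95-fold in expanded clonotypes without the largest. Both of these alternatives keep other clonotypes that carry the TRB of the largest.

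Of 25 genes named in each comparison, 20, 18 and 18 were named again for TRB lineages in clonotypes 1 to 3, and 17 in expanded clonotypes. Without the haemoglobin-rich barcode 21 of 24 measured again kept their direction in clonotype 1, 23 of 24 in clonotype 2, 24 of 24 in clonotype 3 and 22 of 23 in expanded clonotypes, and for TRB lineages 24 of 25 did in expanded families. No paired analysis was possible because there is 1 library of each kind and the labels carry no replicate numbers. The comparison of cycling-like with other cells and its 2 alternatives were not run, since no cluster was cycling-like, and leaving out cycling-like clusters removed no cell. Hbb-bt has no fold without the haemoglobin-rich barcode, nor in clonotype 2 with equal weights. Depth limits genes near 0.135 CPM.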

Other observations

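The tests on single genes of a lineage and on tuft cell genes were chosen only after the result was seen, and of the tests on crossed TCR chains, the measure for a second TRA, the comparison with barcodes of 2 TRB and both tests of marker genes were.

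The third largest TRB lineage, 200 cells with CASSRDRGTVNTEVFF, was not compared above and carried more transcripts of several interferon-inducible genes. Ly6c2, a surface protein of memory CD8 T cells, was 7.98-fold higher (6.54 to 9.69) than in the 3681 other lineage cells. The GTPases Iigp1, Igtp and Gbp4 were 6.44-fold, 4.34-fold and 2.97-fold higher, and the transcription factors Irf8 and Irf1 3.84-fold and 2.73-fold. Ccl5 was at 3292 against 934 CPM. Ifi27l2a, another interferon response gene, was at 0.299 (0.211 to 0.412) and Irf7 at 1.56 (0.989 to 2.35), an interval that includes 1. Interferon response genes had a median of 1.56 (percentile 99.98) and proliferation genes of 1.54 (percentile 100), while memory genes had a median of 0.712 and homing genes of 0.716 (percentile 0 each). Transcripts bound by Regnase-1 had a median of 0.677 (percentile 0.49), and of 0.811 (percentile 2.37) in the lineage of clonotype 2.

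Cluster 9 (55 cells, 0.532%) carried genes of tuft cells, the chemosensory cells of epithelia. Avil, which encodes the actin-binding protein advillin, was at 924 CPM against 8.13 in other cells, the G protein subunit gene Gng13 at 462 against 0.407, Dclk1 at 245 against 1.08 and Pou2f3, the tuft cell master factor, at 79.4 against 0.136. The chemokine gene Xcl1 was at 1991 against 187 CPM. The epithelial genes Epcam and Krt18 had 0 UMIs there. The Gng13-led cluster held 55 to 126 cells in the 5 alternative clusterings.

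For these tuft cell genes, doublets of a T cell and an epithelial cell of like RNA content would lower T cell transcripts to 0.6 of their level or less and raise the UMIs, and the CD3 and Trac sum was at 0.846 (0.780 to 0.916) with median UMIs at 1.24, though the lower bound lies under the 0.8 written down for the opposite outcome. An epithelial cell with less RNA is not excluded, since Tcf7 was at 0.402 and 25.5% of these cells had a TCR chain, against 44.4% of all cells and 24.1% in the B cell-like cluster. Free RNA would give a like level in all clusters built without these genes, whereas with 9 tuft cell genes left out of the clustering their sum was 107-fold higher (93.3 to 123) in a cluster of 44 cells, 41 of them from cluster 9, than in the rest. A single clonotype would put 1 TRA in most cells, and the most frequent took 14.3% of the 14 cells with a TRA (upper bound 42.8), while the 14 cells with any chain fell into 14 clonotypes. No biological explanation was tested, since the design has no other group.

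Chains of different families were found under the same barcode. Of cells with the TRB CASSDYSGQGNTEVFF, 9.98% also had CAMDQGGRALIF, the TRA of clonotype 3. Whether these were 2 cells under 1 barcode cannot be told apart by depth: the median UMIs of cells with a foreign TRA over own-pair cells was 1.04 (1.19 with both TRA, 0.948 with the foreign TRA only), but the bound of 1.2 set before was wrong, since barcodes with 2 TRB of the large lineages were themselves at 1.18. In the largest lineage, 2 cells of like RNA content would put the sum of Mvd, Osr2 and Esm1 at 0.539 of its level in cells with the own TRA. They would also put a UMI of these genes in 55.2% of cells. Against this, the sum was at 0.968 (0.828 to 1.13) with both TRA. Of cells with the foreign TRA only, 39.3% (30.2 to 49.0) had such a UMI, although the sum in these, at 0.474, lies near that of an equal mix. For 1 cell of either kind per barcode, 35.8% was computed with a lineage 1 share of 43.0%. That share was taken from the marker sum of these same cells, so the closeness of 35.8% to 39.3% is no separate support. A TRA rearranged by the lineage itself would raise the share in a few lineages at least 3-fold over the rest, and the highest was 1.56-fold (upper bound 2.06), though shares were not all within 2-fold. Free TCR transcripts may remain: the shares differed 4.38-fold between lineages, above the bound of 3 set before, but the counting interval of 1.81 to 13.8 does not decide. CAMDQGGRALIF had a median of 8.5 to 10 UMIs in the other lineages against 12 in its own. Lower UMIs there were also predicted for free transcripts.

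For the single genes that mark a lineage, such as Jaml and Mylpf, 1 aberrant cell holding most UMIs was found in 2 of 19 lineages, which argues against it as the general cause. A variant shared by donors or strains cannot be told apart, since 6 of the 18 distinct genes, Jaml and Mylpf not among them, were also at least 3-fold higher in another lineage. Activation of a stretch of chromosome, as a vector insertion could give, also stays open. Neighbours within 500 kb had 1806 UMIs against 1698 expected, a ratio of 1.06 (upper bound 1.11). Its interval excludes 1, but it lay within the 0.884 to 1.13 of random genes. Most of the excess came from the neighbours of Serpina3f, with 140 UMIs against 38.5 expected. Serpina3f itself was 14.3-fold higher in another lineage. The neighbours of Jaml had 382 UMIs against 380 expected and those of Mylpf 188 against 172. The ratio was over 1 in 10 of 17 lineages, so the pooled value does not decide. No biological explanation was tested.

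Cells with the TRB of the largest lineage and only a foreign TRA had Mvd, Osr2 and Esm1 at a sum of 429 CPM (350 to 520), between 906 in cells with the lineage's own pair and 69.9 in cells of other lineages with their own. An equal mix of own-pair cells of both sides would give 488 CPM, which lies within that interval. The sum was 876 CPM (759 to 1007) with both TRA, and 127 (67.4 to 217) in cells of other lineages with only the TRA of the largest.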
